A study of Homo sapiens with 6 samples.

How the data were processed

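Total RNA of SKOV3ip1 ovarian cancer cells was copied into biotin-labelled cRNA and hybridised to single-colour Illumina bead arrays, per the labels' protocols, with 3 arrays for control siRNA and 3 for STAT3 siRNA. Group and replicate number were taken from the sample titles. The authors deposited one table of unnormalised probe intensity and one of processed intensity, and BeadStudio is named in the submitters' processing notes without a version. The unnormalised intensities were all positive and came without detection p-values, and whether background had been subtracted is not given in the sources used here. In the processed table every column had a median of 94.2, the columns shared 1 distribution, and the order of probes within an array was that of the unnormalised column (rank correlation 1). Those values are therefore linear and quantile-normalised, with no centring seen, and the method that gave their shared distribution stays unknown.

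The main analysis started from the unnormalised intensities, which were quantile-normalised between arrays and taken to log2 in limma 3.58.1 under R 4.3.3. A normalisation using negative controls was set aside because it needs detection p-values, and no background was subtracted, by a rule written for that case. Any remaining background compresses the fold changes of dim probes. Of 48803 probes, 28098 had 1 gene symbol, 13 had several and 20692 had none in the platform annotation used here. Symbols were updated through a RefSeq gene table of assembly GRCh38.p14, 28059 probes matching by Entrez ID and 14 by accession, while 25 kept the platform's symbol. Probes with a mean above the 40th percentile of probes (intensity 89.9) were kept, and each gene was represented by its tested probe of highest mean log2 intensity, which left 14136 genes. Of 93 further tested probes of the called genes, 78 had the same sign and 15 the opposite sign. List members without a named probe were not analysed here.

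Groups were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Gene lists with at least 5 tested members were compared with the other genes by camera with a preset correlation of 0.01, adjusted over 35 lists. STAT3 was in no list. The genes named are STAT3, then the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, then up to 4 members of each list with the smallest adjusted p, and for STAT3 targets also MYC, BCL2L1, MCL1, BIRC5, CCND1, SOCS3 and VEGFA. Samples, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were median scaling, the authors' processed values, no filter and a stricter one (60th percentile), the mean of a gene's probes, an intensity trend with robust variance, array weights, the replicate number as a block, a test against a fold of 1.2, each array left out, an estimated correlation and fry. A normexp background correction with an offset of 50 and a filter keeping probes above the 75th percentile were added after the data were seen.

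The procedure was tested on simulated data for the siSTAT3 against siCon comparison with 14136 genes. It recovered 41 of 100 genes changed by 0.5 on the log2 scale and 93 of 100 changed by 1, with 5 false calls. The simulated noise was independent between genes and of equal size on all arrays. The measured arrays differed in spread, so the false calls do not give the error rate in these data. No pair of arrays was identical.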

Results

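Expression was measured on 6 single-colour Illumina bead arrays hybridised with RNA of SKOV3ip1 cells, a subline of the human ovarian carcinoma line SKOV3. Cells of 3 arrays had received a control siRNA (siCon) and cells of 3 arrays an siRNA against STAT3 (siSTAT3), a transcription factor activated by cytokine and growth factor receptors. The comparison asks which transcripts depend on STAT3 in these cells. Median unnormalised intensity was 95.9, 95.6 and 93.0 on siCon arrays 1 to 3, and 93.6, 97.1 and 93.5 on siSTAT3 arrays 1 to 3. The number of arrays limits the precision of every value. The labels do not say that the samples were separate cultures, so p-values measure only the spread between these samples, which may be technical. Values are mean intensity ± SD with n = 3 per group, changes are log2 siSTAT3 over siCon ± SE, and adjusted p-values are those of limma.

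STAT3 transcript fell 4.19-fold, from 2521 ± 269 in siCon to 602 ± 60.04 in siSTAT3, on probe ILMN_2401978 (log2 change -2.07 ± 0.12, adjusted p = 2.45e-07). On that probe 23.9% of the control intensity remained. The other STAT3 probes gave 29.8% remaining on ILMN_2410986 (862 ± 42.3 against 258 ± 19.9) and 32.3% on ILMN_1663618 (724 ± 2.27 against 234 ± 7.22). All 3 siSTAT3 arrays lay below all 3 siCon arrays on each of the 3 probes. No background was subtracted here, and the median intensity over all probes was 94.8, so folds of dim genes are understated by whatever background remains.

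**Figure D1:**
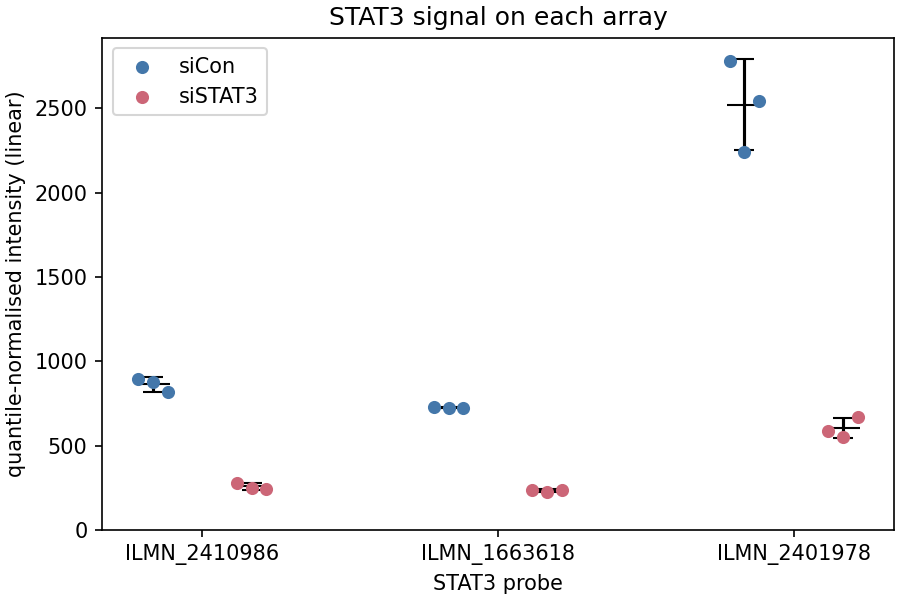
Intensity of the 3 STAT3 probes on each of the 6 arrays, grouped by siRNA, with group means and SD. The representative probe averaged 2521 in siCon and 602 in siSTAT3.

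After STAT3 siRNA, ATF6, HAS3, TUBB2A, IGFBP3 and COL4A1 fell by 2.13-fold to 2.26-fold, and the largest rises were those of BCYRN1 (2.35-fold) and HMOX1 (1.79-fold). Of 14136 genes tested, 207 changed, 151 of them lower and 56 higher. Changes of 2-fold or more were found in 11 genes, of which 10 fell, STAT3 included, and BCYRN1 rose. At an unadjusted p under 0.05 there were 1711 genes, 880 higher and 831 lower, where chance gives 706.8. The groups did not overlap for 2430 genes (17.2%, where chance gives 10%), and all 207 called genes were among them. Array weights gave 437 genes, and a test against a fold of 1.2 gave 31, all lower. The count also depended on single arrays. It was 408 without siCon replicate 3, whose mean correlation with its group was 0.989 and whose score on the first principal component was -23.8 against -1.18 and 0.43 for the other siCon arrays, and 65, 82 and 61 without siSTAT3 replicates 1, 2 and 3.

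**Figure D2:**
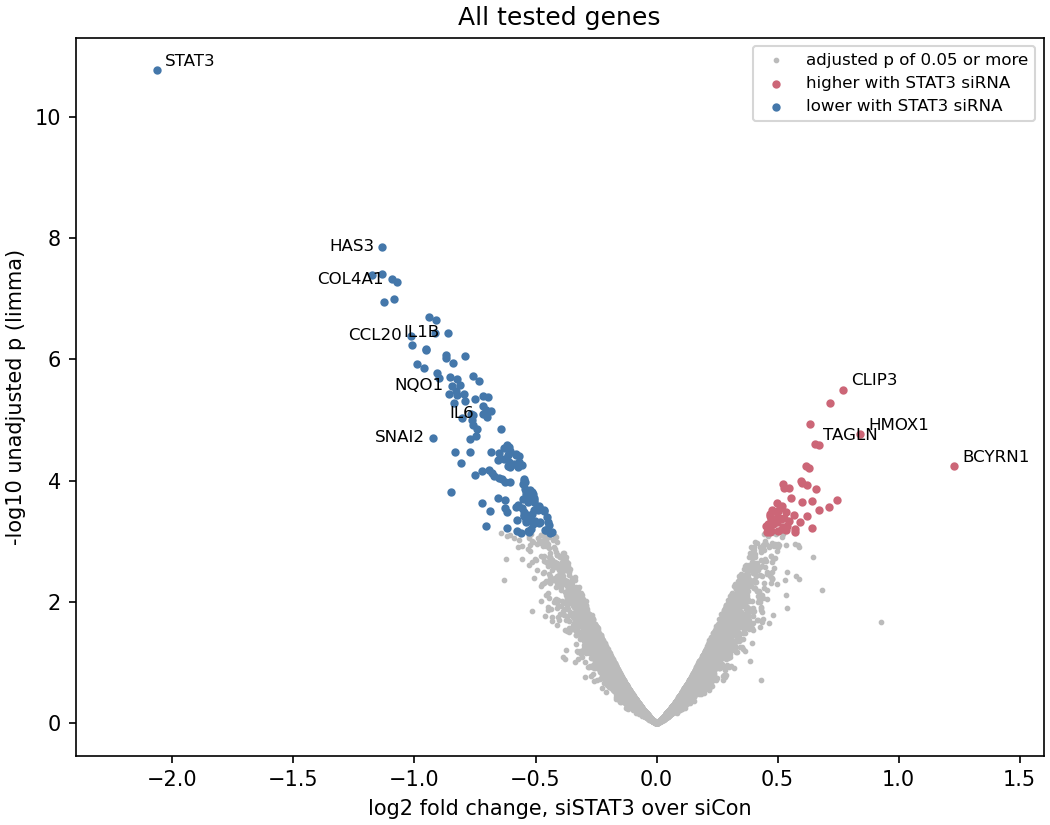
Log2 change after STAT3 siRNA (x axis) against -log10 of the unadjusted limma p-value (y axis) for each of the 14136 tested genes, with called genes coloured by direction. The 151 lower genes outnumber the 56 higher ones, and STAT3 lies farthest to the left.

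Among tested genes other than STAT3, the strongest fall was that of ATF6, a transcription factor of the endoplasmic reticulum stress response, from 1182 ± 150 to 521 ± 36.8 (log2 change -1.18 ± 0.12, adjusted p = 0.000125). HAS3, a hyaluronan synthase, fell from 2642 ± 123 to 1205 ± 68.4 (-1.13 ± 0.10, adjusted p = 9.90e-05), and its other tested probe gave -0.45. COL4A1, a basement membrane collagen, fell from 3246 ± 266 to 1522 ± 113 (-1.09 ± 0.11, adjusted p = 0.000125). IGFBP3, a secreted binding protein of insulin-like growth factors, fell 2.19-fold on its representative probe, and its other probe gave -1.08. The chemokine CCL20 (728 ± 84.6 to 360 ± 38.7), the collagenase MMP1 (548 ± 77.8 to 271 ± 28.2) and the ectonucleotidase NT5E (1751 ± 230 to 901 ± 70.9) fell with adjusted p-values of 0.000447, 0.000599 and 0.000616. The tubulin TUBB2A, which has a close copy in TUBB2B, fell 2.19-fold, the dynein light chain DYNLT1 2.10-fold, the dynein assembly factor DAW1 2.12-fold and the RNA helicase DDX21 1.95-fold. SCG5, a secretory granule chaperone, fell 1.99-fold with an adjusted p of 0.000805. These 12 genes passed the threshold under each of the 16 alternatives that test against no change.

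Among tested genes the largest rise past the threshold was that of BCYRN1, a small noncoding RNA made by RNA polymerase III, from 837 ± 403 to 1842 ± 249 (log2 change 1.23 ± 0.22, adjusted p = 0.00977). The call was lost without siSTAT3 replicate 1 or 3, with adjusted p-values of up to 0.103. HMOX1, the inducible heme oxygenase, rose from 254 to 458 (0.84 ± 0.14, adjusted p = 0.0044). CLIP3, a protein of the trans-Golgi network, rose from 239 ± 22.6 to 407 ± 14.03 (0.77 ± 0.11, adjusted p = 0.00144). The adhesion receptor ADGRG1 rose 1.64-fold (adjusted p = 0.00179; its other probes gave 0.81 and, near background, 0.02), the actin-binding protein TAGLN 1.57-fold (adjusted p = 0.00596) and the mitochondrial adenylate kinase AK4 1.59-fold (adjusted p = 0.00609). For AK4 the 3 other probes gave -0.01, 0.10 and 0.05, and the call was lost when a gene's probes were averaged. The exonuclease ISG20, the desaturase SCD, the lipid droplet protein HILPDA, the calcineurin subunit PPP3R1, the splicing factor RBM39 and TMEM150A rose by 1.56-fold to 1.68-fold, with adjusted p-values from 0.0183 to 0.0445. Each of these last 6 lost its call without at least 1 siSTAT3 array, and the other RBM39 probe gave 0.06. CLIP3 and ADGRG1 passed under each of the 16 alternatives that test against no change, and no higher gene passed a test against a fold of 1.2.

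**Figure D3:**
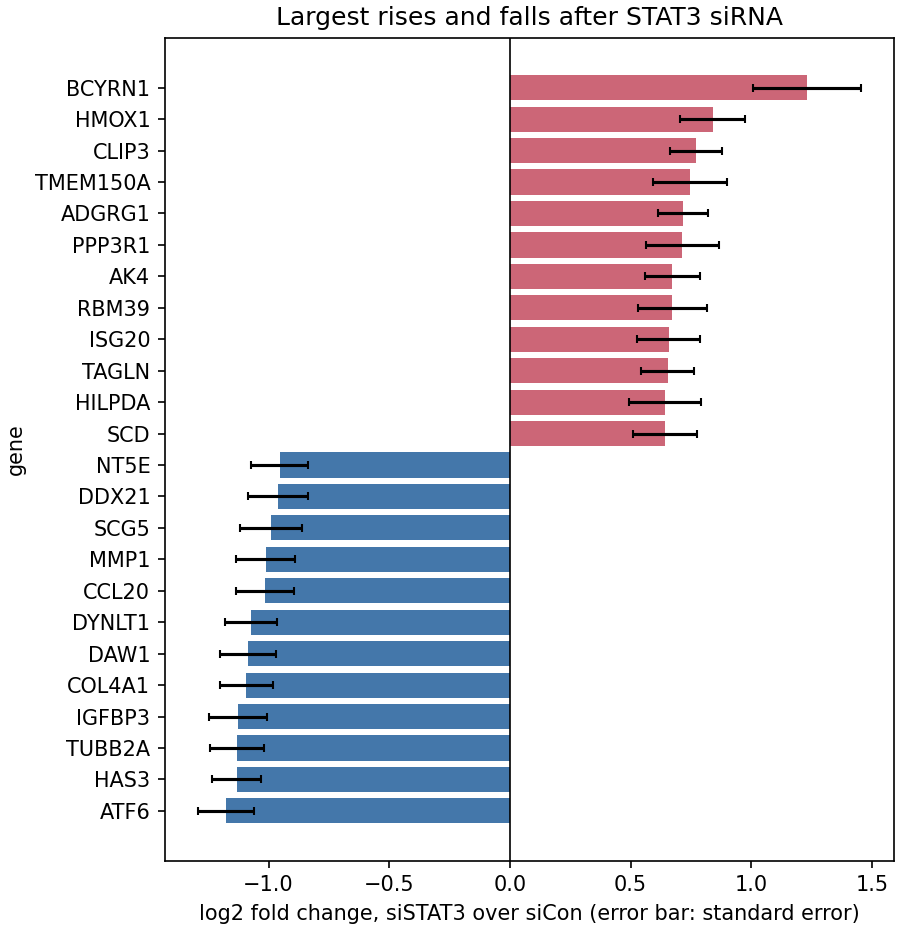
Log2 change with SE for the 12 genes with the largest rises and the 12 with the largest falls. Rises run from 0.64 (SCD) to 1.23 (BCYRN1) and falls from -0.95 (NT5E) to -1.18 (ATF6).

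Of 35 gene lists, 11 shifted by camera with a preset correlation of 0.01 between genes, 8 lower and 3 higher. Some lists share members, so the 11 are not separate results. MMP1 is in the STAT3 target and matrix protease lists, and IRF9 in the STAT3 target and interferon-stimulated lists. None of the 35 passed with a correlation estimated per list. The adjusted p of 0.34 shared by several lists is a tie from the adjustment, not a separate result for each. Among the shifted lists the estimate was under 0.01 for G1/S and DNA replication (0.005), NF-kB (0.009) and unfolded protein response (-0.011). It lay above 0.01 for the rest. Camera's unadjusted p for G1/S and DNA replication still rose from 3.24e-05 to 0.0111. A lost call therefore does not by itself show that a shift rested on correlation. By fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, the lists of G1/S and DNA replication and of NF-kB and inflammatory cytokines passed, each with an adjusted p of 0.0497.

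STAT3 target genes shifted lower (mean -0.11, adjusted p = 0.00277 by camera, adjusted p = 0.34 with an estimated correlation). Among 42 measured members 1 rose, 3 fell and 38 did not pass, and adjusted over the list alone 1 rose and 4 fell. IL6ST, the shared receptor chain gp130, fell from 1574 to 1053 (-0.57, adjusted p = 0.0487), with its other probes at 0.22 and -0.02. MMP1 and the transcription factor FOS (314 to 224, -0.49, adjusted p = 0.0273) also fell, while IRF9, a DNA-binding partner in interferon signalling, rose from 369 to 568 (0.62, adjusted p = 0.0161). Members often named as STAT3 targets did not pass. MYC gave -0.24, BCL2L1 -0.27, MCL1 -0.28, BIRC5 -0.20, CCND1 -0.10 and VEGFA 0.07. SOCS3 lay near background at 101 in both groups. So did other members that did not pass, among them MMP2, MMP9, MMP14, IL6R, FGB, HGF and IL11, where a change would hardly show.

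NF-kB and inflammatory cytokine genes shifted lower (mean -0.13, adjusted p = 0.0273 by camera, adjusted p = 0.34 with an estimated correlation), with 5 of 29 measured members lower, none higher, and 7 lower adjusted over the list alone. IL1B fell from 649 to 357 (-0.86, adjusted p = 0.000436) and CXCL1, a neutrophil chemokine, from 2542 to 1704 (-0.58, adjusted p = 0.00934), beside CCL20. The cytokine IL6 fell from 3147 to 1914 (-0.72, adjusted p = 0.00248), and the remaining called member was CXCL2 (-0.66), named after its value was seen. The list's call was lost without siCon replicate 1 (adjusted p = 0.0585), siCon replicate 2 (0.0586), siSTAT3 replicate 1 (0.0526) or siSTAT3 replicate 2 (0.0757). Interferon-stimulated genes shifted higher (mean 0.09, adjusted p = 0.0182 by camera, adjusted p = 0.34 with an estimated correlation), with 2 of 42 higher and none lower, and 6 higher adjusted over the list alone. IRF9 and ISG20 passed, and IFI35 (0.49, adjusted p = 0.0504) and GBP1 (0.43, adjusted p = 0.0906) did not. GBP1 passed without siCon replicate 3 (adjusted p = 0.0137). Members went both ways, with MX1 at 0.16, ISG15 at -0.13 and IFITM1 at -0.37, chosen after their values were seen and none past the threshold. The list's adjusted p was 0.103 without siCon replicate 3, 0.138 without siSTAT3 replicate 2, 0.0547 with array weights and 0.0743 with probes above the 75th percentile.

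Mesenchymal and EMT genes shifted lower (mean -0.14, adjusted p = 0.0117 by camera, adjusted p = 0.34 with an estimated correlation). Of 24 measured members 5 fell and 1, TAGLN, rose, and adjusted over the list alone 7 fell and 1 rose. SNAI2, a repressor of epithelial genes, fell from 1368 to 738 (-0.92, adjusted p = 0.00489), the matricellular protein CCN2 from 2534 to 1658 (-0.61, adjusted p = 0.00982) and the matrix protein TGFBI from 3323 to 2333 (-0.51, adjusted p = 0.0224). The remaining falls, named after their values were seen, were SPARC (-0.49) and CCN1 (-0.53). Without siCon replicate 1 the list's adjusted p was 0.0839. Matrix protease, integrin and invasion genes shifted lower (mean -0.11, adjusted p = 0.0112 by camera, adjusted p = 0.34 with an estimated correlation), with MMP1 and the lysosomal protease CTSL (5268 to 3610, adjusted p = 0.014) as the 2 of 45 that fell, and 4 lower adjusted over the list alone. PLAUR gave -0.47 and MMP10 -0.44, each with an adjusted p of 0.0836. Both genes passed without siCon replicate 3, with adjusted p-values of 0.00287 for PLAUR and 0.0291 for MMP10. The list's adjusted p was 0.0653 without siCon replicate 3 and 0.0542 without siSTAT3 replicate 2. Epithelial genes did not pass (adjusted p = 0.669), with KRT8 (-0.52) the 1 of 23 that fell.

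Genes of G1/S and DNA replication shifted lower (mean -0.12, adjusted p = 0.000566 by camera, adjusted p = 0.34 with an estimated correlation). Among 43 members 2 fell, and 3 adjusted over the list alone. The replicative helicase subunit MCM3 fell from 6277 to 4336 (-0.54, adjusted p = 0.0329), its other probe giving -0.51, and the polymerase subunit POLE2 from 1192 to 851 (-0.48, adjusted p = 0.0385). E2F3 gave -0.38 and TK1 -0.35. Mitosis genes shifted lower (mean -0.08, adjusted p = 0.0119 by camera, adjusted p = 0.34 with an estimated correlation), with CDCA8, a subunit of the chromosomal passenger complex, the 1 of 47 that fell (1399 to 964, adjusted p = 0.0187), also adjusted over the list alone. Without siCon replicate 3 the mitosis list had an adjusted p of 0.105.

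Unfolded protein response genes shifted lower (mean -0.11, adjusted p = 0.0234 by camera, adjusted p = 0.34 with an estimated correlation). ATF6 and the lectin chaperone CANX (1499 to 1058, adjusted p = 0.0236) were the 2 of 28 that fell, and adjusted over the list alone 7 fell and 1 rose. XBP1 gave -0.43 and SLC7A11 -0.39. The list's adjusted p was 0.0518 without siCon replicate 1, 0.102 without siCon replicate 2, 0.0557 without siSTAT3 replicate 3 and 0.0821 with no filter. Heat shock genes shifted lower (mean -0.13, adjusted p = 0.0106 by camera, adjusted p = 0.34 with an estimated correlation) with none of 17 members past the threshold, and 3 lower adjusted over the list alone. SERPINH1 gave -0.47, HSPA1A -0.40 and HSPH1 -0.40. Without siCon replicate 3 the heat shock list had an adjusted p of 0.0862. In that fit SERPINH1 passed (-0.60, adjusted p = 0.00246), while HSPA1A and HSPH1 did not.

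Oxidative phosphorylation genes shifted higher (mean 0.14, adjusted p = 0.000287 by camera, adjusted p = 0.52 with an estimated correlation), 42 of 54 members lying above 0 and none passing, over all genes or adjusted over the list alone. The members with the smallest p-values were NDUFS4 (0.38), COX7C (0.39), NDUFB8 (0.40) and NDUFC1 (0.34). On siCon replicate 3 the list lay at -0.25 relative to the mean of all arrays, against 0.01 to 0.12 on the other 5, and without that array its mean was 0.05 and its adjusted p 0.132. Glycolysis genes shifted higher (mean 0.11, adjusted p = 0.0182 by camera, adjusted p = 0.36 with an estimated correlation), with the aldolase ALDOC (414 to 573, adjusted p = 0.0487) the 1 of 22 that rose, 2 adjusted over the list alone, and ENO2 at 0.41. Without siCon replicate 1 the glycolysis list had an adjusted p of 0.174 and without siSTAT3 replicate 3 one of 0.104.

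**Figure D4:**
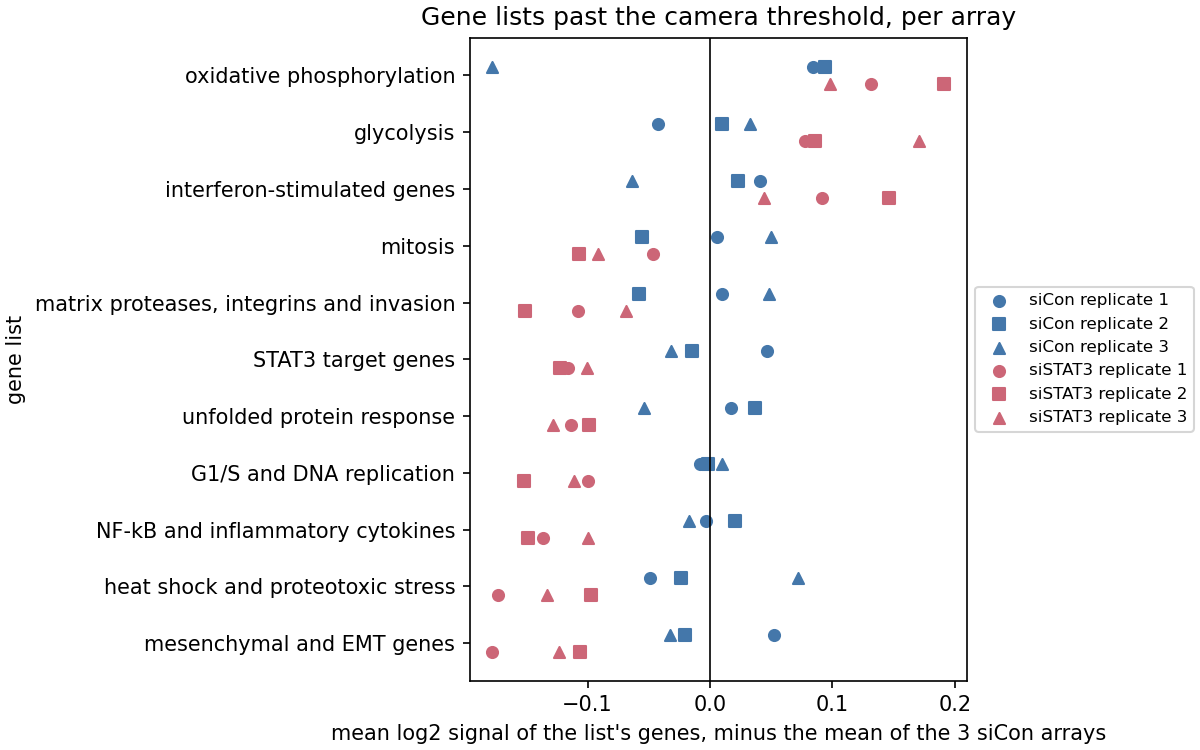
Mean log2 intensity of the genes of each of the 11 lists past the camera threshold on each array, minus the mean of the 3 siCon arrays (x axis), 1 point per array. On oxidative phosphorylation, siCon replicate 3 lies far below the other 5 arrays.

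The other lists did not pass by camera in the main analysis, though single members changed. Unless stated, calls in this paragraph are over all genes, and adjusted over the list alone further members passed in several of these lists. In the NRF2 list (adjusted p = 0.175) HMOX1 rose and NQO1, a quinone reductase, fell from 5643 to 3159 (-0.84, adjusted p = 0.00129). In the hypoxia and angiogenesis list (adjusted p = 0.343) the hypoxia-inducible factor EPAS1 fell from 1083 to 737 (-0.56, adjusted p = 0.00952), THBS1 from 4514 to 2693 (-0.72, adjusted p = 0.0249) and FGF2 by a log2 change of -0.56. Among Wnt and Notch genes (adjusted p = 0.145, 0.0424 with array weights, and adjusted p = 0.52 with an estimated correlation) the Wnt inhibitor DKK1 fell from 1192 to 764 (-0.64, adjusted p = 0.00373). Cholesterol biosynthesis (adjusted p = 0.178) held a rise of HMGCS1 (0.51, adjusted p = 0.0287) and fatty acid synthesis (adjusted p = 0.178) the rise of SCD. Pro-apoptotic genes (adjusted p = 0.175) held a fall of TNFSF10 (-0.51) and a rise of BAX (0.57), whose other probes gave 0.00 and 0.09. Of anti-apoptotic genes (adjusted p = 0.669) none of 12 passed over all genes. Adjusted over the list alone, BCL2L2 (0.40) and BIRC6 (0.38) were higher. BIRC6 passed over all genes without siCon replicate 3 (limma adjusted p = 0.0279). CTSC (-0.59), CTSL and ATG12 (-0.47) were the 3 lysosome and autophagy genes that fell (adjusted p = 0.837), PPAT (-0.83) fell in ribosome biogenesis and MYC targets (adjusted p = 0.178), DUSP1 (-0.44) in receptor tyrosine kinases, RAS and ERK feedback (adjusted p = 0.297), PRKRA (-0.54) in microRNA machinery (adjusted p = 0.837) and H2AZ2 (-0.55) in histones (adjusted p = 0.669). JAK-STAT components (adjusted p = 0.575) held the falls of IL6 and, on its representative probe only, IL6ST. Cyclin-dependent kinase inhibitors and p53 target genes (adjusted p = 0.575) held the rise of BAX.

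No list of markers of other cell types passed by camera in the main analysis. Leukocyte markers (12 measured, adjusted p = 0.366), endothelial markers (10, adjusted p = 0.392) and neural markers (9, adjusted p = 0.837) held no gene called over all genes. ENO2 was the 1 called adjusted over the list alone, in the neural list. Apart from CD68, MBP and ENO2, the markers in these lists lay near the median intensity of all probes (94.8). A change would hardly show there, so these lists say little about other cell types. LRRN4 (-0.52, adjusted p = 0.0191) was the 1 of 11 fibroblast and mesothelial markers that fell. That list's mean was -0.12 and its adjusted p 0.0612, and it passed under median scaling (0.0342) and with array weights (0.0337), with adjusted p = 0.34 with an estimated correlation. Ovarian carcinoma markers (20, adjusted p = 0.175) held none over all genes and 4 lower adjusted over the list alone, MSLN giving -0.41 and FOLR1 -0.53. No member passed in the lists of PI3K, AKT and mTOR (adjusted p = 0.593), cytosolic ribosomal proteins (0.214, 0.0416 under median scaling, and adjusted p = 0.68 with an estimated correlation), proteasome (0.947) or housekeeping genes (0.995). The mean and median had opposite signs for microRNA machinery (-0.03 and 0.07), lysosome and autophagy (-0.01 and 0.01) and housekeeping genes (0.00 and -0.02).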

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

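The count over other splits of the arrays was chosen after the result was seen. So was the test, well above background, on RNAs of classes that largely lack poly(A) tails. Among probes that the annotation used here gives no single gene, 9918 passed the filter, and 5 of them passed the threshold, a signal in probes outside the comparison of named genes. One rose (ILMN_1772207, 0.68, adjusted p = 0.0329) and 4 fell, the strongest being ILMN_2387385 (-1.28, adjusted p = 4.61e-05). Of the 10 splits of the 6 arrays into 3 and 3, the labelled split with 207 called genes was the 1 with as many, and the highest of the others called 0. With 10 splits a share under 0.05 cannot be reached.

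Oxidative phosphorylation genes shifted higher as a list by camera with the preset correlation, while no member passed. The list's adjusted p was 0.52 with an estimated correlation and 0.36 by fry. Random lists matched on intensity and gene span argue against a shift shared by all such genes, since the list's median of 0.16 lay at percentile 100 of 10000 lists, whose median was 0.02. A position of siCon replicate 3 apart from the other arrays is consistent with most of the shift, since 36.7% of the mean was left without it. The median without that array was 0.05, at percentile 98.5 of matched lists, and the list's camera adjusted p was 0.132. Matched lists draw genes at random and do not carry any shared movement of this list's genes between arrays. The percentiles therefore do not measure chance. A smaller effect of STAT3 siRNA stays open.

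More called genes were lower than higher, though at an unadjusted p under 0.05 there were 880 higher and 831 lower. The lower share of called genes was 61.8% with array weights, 63.0% without siCon replicate 3, and 87.7% to 93.4% without a siSTAT3 array, so its size depended on the threshold, the model and the arrays used. The lower share was 72.9% in the main analysis and at lowest 71.7% under median scaling or the authors' values. These shares argue against the choice among these scalings as the source. All of them give the arrays a common centre, and the authors' values are quantile-normalised like the main analysis. A scaling without a common centre was not tried, so scaling as such stays open. Silencing of other transcripts by the siRNA cannot be told apart from an effect of STAT3 loss, because the siRNA's sequence is not given in the sources used here. Of the 150 lower genes other than STAT3, 3 (2%) were on the STAT3 target list (Fisher's exact test, two-sided, odds ratio 7.30, p = 0.00994). Among these was IL6ST, whose other probes did not show the fall, as given above. The test takes genes as independent and covered the lower genes only. IRF9, among the 56 higher genes, was on the list too, so the overlap is not shown to belong to the falls. The overlap does not decide between silencing of other transcripts and STAT3 loss.

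BCYRN1 and the ribosomal RNA gene RNA28SN5 (3726 to 5655, log2 change 0.60, adjusted p = 0.0249; chosen after its values were seen) both rose. They were compared with 90 others chosen as rRNA, small noncoding RNA or replication-dependent histone genes, classes that largely lack poly(A) tails. Whether each of the 90 lacks a tail was not checked. Their median was -0.0214 on the log2 scale. Of them, 63 lay under 2 times the median probe intensity, where a rise would hardly show, so that value decides nothing. Over the 27 brighter ones the median was -0.0754, with 9 above 0 and 0 past the threshold. Its bootstrap SE of 0.0434 was taken over genes and does not hold the spread between arrays. These values argue against a median rise of 0.3 or more among these 27, most of which are still dim enough for background to compress a rise. The brightest of them split, RN7SL1 giving -0.14, H2BC12 0.18 and H4C3 0.68. An effect of siCon replicate 3 is argued against too, at least 87.1% of each change being left without it. A rise of a few such RNAs was not tested and stays open beside an effect of STAT3 siRNA, the histone gene H4C3, singled out after its values were seen, giving 0.68 (adjusted p = 0.163) and 0.38 without siCon replicate 3.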

How the results depend on the processing

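The normexp correction and the filter at the 75th percentile were chosen after seeing the data. STAT3 passed under all 16 alternatives that test against no change, its log2 change lying between -2.15 and -1.81. Changed genes numbered 207 in the main analysis and 138 under median scaling, where 99 were lower. Array weights gave 437 (167 higher, 270 lower). The test against a fold of 1.2 gave 31, with 0 higher and 31 lower. With the replicate number as a block, 283 genes changed, 100 of them higher. The design fixed beforehand did not take the numbers as pairs. Same-numbered arrays correlated at 0.05, 0.18 and 0.07 in their deviations, and each siCon array correlated best with the siSTAT3 array of its own number. The best partners of the siSTAT3 arrays were not checked, so a pairing stays open. Leaving out 1 array gave 61 to 408 changed genes, 4 to 151 higher and 57 to 257 lower, the low counts without a siSTAT3 array and the high ones without siCon replicate 3. The cause was not tested. Shifted lists numbered 11, then 6 to 10 with an array left out, 0 with an estimated correlation and 10 to 13 under the other camera alternatives, while fry, which tests a list against no change, passed 2. Among the other camera alternatives, interferon-stimulated genes lost their call with array weights and with the 75th percentile filter, and the unfolded protein response with no filter. Fibroblast and mesothelial markers gained one under median scaling and array weights, Wnt and Notch under array weights, and cytosolic ribosomal proteins under median scaling. Of 55 named called genes other than STAT3, 19 passed under each of the 16 alternatives that test against no change and 35 under each of those that keep all 6 arrays, and none changed direction while past the threshold. Running without background correction is the main analysis itself, and a chip block was not run because the chip is not given in the sources used here. Signal over background limits dim genes, whose folds are understated by any background left.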

Other observations

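The genes and lists in this part were chosen after the values were seen. EFEMP1, a fibulin, fell from 327 to 171 (-0.94, adjusted p = 0.000322), the Wnt antagonist SFRP1 from 309 to 168 (-0.87, adjusted p = 0.000682) and the microfibril protein MFAP5 from 6025 to 3462 (-0.80, adjusted p = 0.00155). The growth factor binding protein IGFBP1 (-0.75), the decoy receptor TNFRSF11B (-0.70), the plasminogen activator PLAT (-0.63) and the collagen COL8A1 (-0.62) fell as well. These genes were picked singly, and no group that holds them was tested.

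CCN1, CCN2, MYOF, NT5E and IGFBP3, known as targets of the YAP and TEAD transcription regulators, all fell. The hypothesis that such targets fell as a group was tested on 19 other members, of which 17 lay below 0 and none was called (mean -0.11). Camera gave an adjusted p of 0.0262 over 3 lists, and the adjusted p was 0.139 with an estimated correlation. Several of the 19 members lay near background, among them AMOTL1, AMOTL2, RBMS3 and CCDC80. The falls that prompted the list came from the same arrays, so the other members are no independent support. Lower YAP and TEAD output beside STAT3 siRNA stays a hypothesis, whose list passed only with the preset correlation.

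The falls of FOS, FOSB (-0.61), DUSP1, SGK1 (-0.55) and ETS2 (-0.84) raised the hypothesis of a lower immediate-early response. The 20 other immediate-early genes had a mean of -0.06 and did not pass (camera adjusted p = 0.112, adjusted p = 0.364 with an estimated correlation). Without siCon replicate 3 camera gave an adjusted p of 0.019, so the group stays open. SSR1 (-0.77), SAR1B (-0.77), TMED2 (-0.65) and CANX fell, while 39 other genes of endoplasmic reticulum translocation and COPII transport had a mean of -0.01 and an adjusted p of 0.605, with no shift of the group detected.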
